A study of Rattus norvegicus with 192 samples.

How the data were processed

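The libraries are TempO-Seq profiles of primary hepatocytes from male rats, exposed for 24 h. Each library was assigned to its chemical, dose and plate from the submitters' labels, in which a well name gives the plate. DMSO replicates 1 to 9 carry the submitters' numbers, which name libraries and pair nothing. The labels give no batch beyond the plate, and plates 1, 2 and 3 hold 90, 90 and 12 libraries. They do not say whether wells come from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. The labels describe a log2 step between doses, but the doses lie about 3-fold apart and were used.

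The deposited table holds whole-number counts per probe for 22253 probes, raw counts by the authors as far as the values show. Reads were aligned with Bowtie, per the submitters' processing notes, with its version, the probe sequences and the genome build not given in the sources used here. Probes carry a gene symbol and a number, and 21143 symbols occur, of which 987 have more than 1 probe. Of these symbols 15522 were found in the RefSeq gene table of assembly GRCr8 (17302 with synonyms), which was used for names alone. A further 1933 symbols carry a decimal suffix, such as Gsta50.81, and are printed as the file gives them. Their meaning is not stated, and close paralogs such as the Gsta, Ugt2b, Cyp2b, Cyp3a and Cyp4a genes can share probes, so single members of these families are uncertain. All columns were matched to a library, 0 were left unmatched and 0 held the same values as another. Where a list gene has several probes, the probe with the highest mean count stands for it.

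Ligation products are amplified before counting, so counts are not independent molecules, and intervals reflect the spread between libraries as modelled. Probes were tested if they had at least 1.741 CPM (10 counts at the median depth) in at least 6 libraries, which left 11055. In R 4.3.3, edgeR 4.0.16 was used with TMM scaling and its quasi-likelihood F test, plate as a factor, and Benjamini-Hochberg adjustment with a threshold of 0.05. For each chemical the tested term was the dose score log2(1 + dose in µM) over its 6 libraries and the 9 DMSO libraries, printed as the fitted log2 change at 33.3 µM with its SE. Class trends are means of such slopes in 1 model for azoles, chloroacetamides, perfluorinated acids and triazines, and 4 differences between related chemicals are contrasts of slopes at doses that both sides have. The 9 reference libraries were each tested against DMSO with an indicator, as was each treated library, and each DMSO library against the other 8. The effect of plate among DMSO libraries was tested over 3 plates. Library comparisons used log2 CPM with a prior count of 2, and the library score used 5533 probes with a mean log2 CPM above 4.

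Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists and fits of a kind. Of 22 lists 20 could be tested. These are genes induced through AhR, CAR and PXR, PPARα, NRF2, FXR, the glucocorticoid receptor and p53, genes that respond to oestrogen, and genes of cholesterol synthesis, fatty acid synthesis, bile acid synthesis, the integrated stress response, the unfolded protein response, heat shock, the cell cycle and inflammation. Markers of hepatocytes, macrophages, endothelial cells and stellate cells make up the rest. Markers of bile duct cells had 1 tested gene and transcripts of the mitochondrial genome had 0 probes, so neither gave a result. For single reference libraries the median of a list was placed among 10000 random lists matched on mean expression. Lists, tests, filters and the rule for named genes were fixed before the data were examined. That rule took, for each class trend and each difference, up to 10 called probes with the highest and 10 with the lowest change that had a mean count of at least 10 and the same sign without the highest doses. For each chemical it took up to 3 and 3, for each reference chemical up to 5 and 5, for a list up to 4 members with the smallest adjusted p and those that went against it, and the genes of a fixed panel at any time. Names beyond it are said to be chosen after their values were seen, some genes that it names are not reported here, and these include genes picked by the same rule without DMSO replicate 1.

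Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, no plate term, a dose score by rank and an estimated list correlation. The highest doses, each DMSO library (for a chemical's trend, replicate 1 and those of its plate) or, for azoles and chloroacetamides, each member were left out. Fits without DMSO replicate 1 for chemicals of plates 2 and 3, for lists and for lowest active doses, the comparison of plates without each DMSO library, fits with the library score as a covariate, both together, and leaving out each lower dose were added after the data were seen. Steps were tested on simulated counts with the real layout, with 100 of 11055 probes changed at each size. With the spread of all DMSO libraries, changes of 1 and of 2 on the log2 scale were recovered in 9% and 77% of probes for the PFOA trend, 100% and 100% for the azoles, 48% and 100% for the perfluorinated acids, 15% and 92% for PFOA minus PFOS, 0% and 13% for 1 library of WY14643 and 2% and 73% for the plates. With the smaller spread estimated without DMSO replicate 1, the PFOA trend recovered 35% and 99%, with all 9 DMSO libraries still in the simulated fit. Changed probes were drawn from those with higher counts, and all probes and libraries were given 1 common spread. Recovery for probes with low counts, or with 1 library that stands apart, was therefore not tested.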

Results

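Gene expression was measured in libraries of primary hepatocytes from male rats, liver cells plated on collagen. The assay was TempO-Seq, a targeted form of RNA sequencing in which pairs of detector oligonucleotides that anneal side by side on a transcript are ligated, amplified and counted. Cells were exposed for 24 h in 0.1% DMSO, the solvent. There were 29 chemicals at 6 doses each (174 libraries, 1 per dose), 9 reference chemicals at 1 dose each (9 libraries) and 9 DMSO libraries, 3 on each of 3 plates. The highest dose was 100 µM for 16 chemicals and 33.3 µM for 13, and neighbouring doses differed 2.86-fold to 3.08-fold. Total counts per library ran from 582071 to 11249014 with a median of 5745085, and from 1340300 to 11249014 in the 174 dose libraries. The DMSO libraries held 2876741 to 8513985 counts. The question put by the design is which transcripts each chemical changed and from which dose.

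DMSO replicate 1, on plate 1, differed from the other 8 DMSO libraries in a large share of transcripts. Its correlation with each of them, over log2 CPM (counts scaled to the library total), was 0.577 to 0.779, against 0.853 to 0.991 for the 28 pairs among replicates 2 to 9. Pfn1, which encodes the actin-binding protein profilin, stood 7.72 higher in it on the log2 scale, and the complement gene Cfb 5.66 higher. The purine synthesis gene Atic was at -5.28 and the NRF2-inducible gene Akr1b8 at -4.50. These values are fitted changes from the test described next. In edgeR's quasi-likelihood test of 1 DMSO library against the other 8, replicate 1 had 5595 of 11055 probes with an adjusted p under 0.05, and 8 of 8 others had 0 (14 to 862 at an unadjusted p under 0.05), with DESeq2 not run on these. With replicate 1 left out of the controls, replicate 5 had 1467 called probes (685 higher and 782 lower), and replicates 2, 3, 4, 6, 7, 8 and 9 still had 0. No pair of DMSO libraries was close enough to be 1 library deposited again, the smallest chi-square per degree of freedom being 3.12. Because of replicate 1, the main counts below are also given without it. Between the 3 plates, the DMSO libraries showed 0 called probes in edgeR, with 546 at an unadjusted p under 0.05 and 0 called by DESeq2.

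A further difference among libraries ran along the direction in which DMSO replicate 5 departed from the other DMSO libraries of plate 2. It involved higher Mgmt (3.12 on the log2 scale), Apoa5 (2.25) and Cebpb (2.09) and lower Aldh6a1 (-6.88), Gna13 (-6.45) and Med6 (-6.19). A score for each library along this direction had an absolute correlation of 0.991 across all libraries with their first principal component, which held 30.1% of the variance. The score was above 0.5 in 12 treated libraries of 8 chemicals, and 3 of the 12 were at a highest dose. The PFOA library at 100 µM had a score of 1.72.

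**Figure D1:**
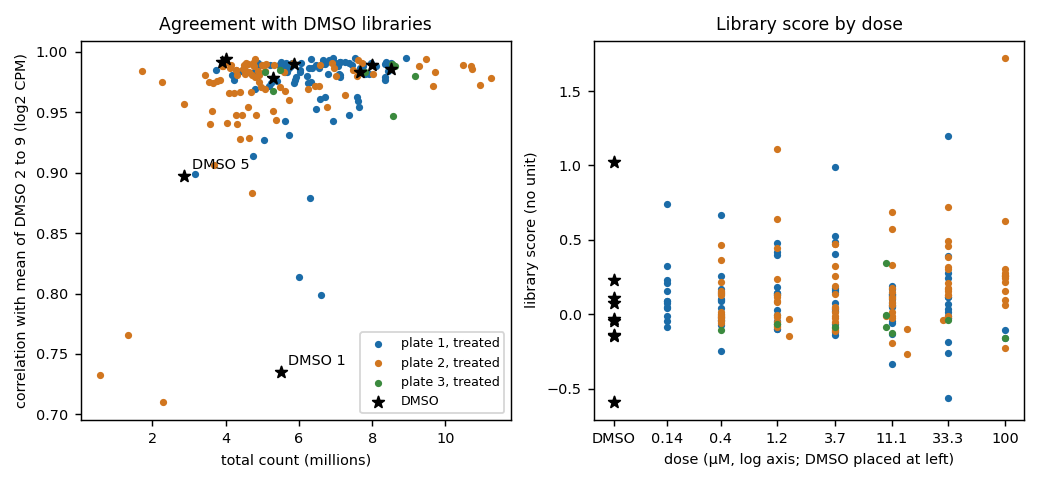
Left, Pearson correlation of each library with the mean of DMSO replicates 2 to 9 over log2 CPM, against its total count, coloured by plate, with DMSO libraries as stars. Right, the library score against dose in µM on a log axis with DMSO at the left; DMSO replicate 1 lies far below the other DMSO libraries at left, and DMSO replicate 5 lies high at right.

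Some of the 9 reference chemicals, each measured in 1 library, changed transcripts of the receptor or pathway they are known to act on. With WY14643, a PPARα agonist, Acot1 rose by 9.57 ± 0.82 on the log2 scale (SE), Ehhadh by 6.85 ± 0.55 and Pdk4 by 4.55 ± 0.58, the largest adjusted p of these being 0.0175. Acot1 is an acyl-CoA thioesterase, Ehhadh a peroxisomal β-oxidation enzyme and Pdk4 a kinase that inhibits pyruvate dehydrogenase. With oltipraz, an inducer of NRF2 genes, Nqo1 rose by 2.56 ± 0.29 (adjusted p = 0.0345), and with sulforaphane, another such inducer, Hmox1 rose by 3.48 ± 0.53 (adjusted p = 0.00614). With dexamethasone, the conjugating enzyme gene Ugt2b10 rose by 3.19 ± 0.33 (adjusted p = 0.0243). This gene is in none of the gene lists, and its rise is not tied to the glucocorticoid receptor here. Pdk4 with WY14643 lost its call without DMSO replicate 4, 5, 6, 7, 8 or 9 (the change then at 4.32 to 4.82). Nqo1 with oltipraz lost it without 2, 3, 4, 5, 6, 7, 8 or 9 (2.51 to 2.63). Ugt2b10 with dexamethasone lost it without 2, 4, 5, 6, 7, 8 or 9 (3.11 to 3.29). These fits kept DMSO replicate 1. Without replicate 1 the calls held, at 4.57 ± 0.29, 2.56 ± 0.17 and 3.19 ± 0.20 in this order. The lone library is assumed to vary as DMSO does, and nothing repeats it.

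Several changes of reference chemicals passed the test once DMSO replicate 1 was left out. These were Cyp3a23/3a1 with dexamethasone, at 3.50 ± 0.22 (adjusted p = 7.52e-05), and with pregnenolone-16alpha-carbonitrile, a PXR ligand, at 3.37 ± 0.23 (adjusted p = 0.000201). Cyp2b2, a cytochrome P450 gene induced through CAR, was at 4.93 ± 0.55 with TCPOBOP (adjusted p = 0.0286), and the AhR gene Cyp1a1 at 5.95 ± 0.62 with oltipraz (adjusted p = 0.00211). Counts of called probes with all DMSO libraries, and then without replicate 1, were 1323 and 3147 for sulforaphane, 15 and 59 for WY14643, 2 and 144 for oltipraz, and 1 and 14 for dexamethasone. For pregnenolone-16alpha-carbonitrile they were 0 and 166, for GW4046 0 and 105, for TCPOBOP 0 and 2, for 17beta-estradiol 0 and 1, and for testosterone 0 and 0. The 5 chemicals with 0 in edgeR had 123 to 639 probes at an unadjusted p under 0.05 and 0 to 47 called by DESeq2. Sulforaphane's library was the shallowest of all, and its 5 lowest fitted probes, Cd36 among them, had 0 counts in it. As a description, the median of the 26 PPARα genes with WY14643 was 1.96, above all of 10000 random lists matched on expression (percentile 100). That of the 20 NRF2 genes with oltipraz was 1.60 (percentile 100), and with sulforaphane 0.43 (percentile 99.3). That of the 3 FXR genes with GW4046 was 0.82 (percentile 99.5), but which compound this name stands for is uncertain, so the value is not tied to FXR here. The 18 CAR and PXR genes had a median of 0.12 with pregnenolone-16alpha-carbonitrile (percentile 84.1), -0.03 with TCPOBOP (percentile 46.9) and 0.47 with dexamethasone (percentile 100). The 4 oestrogen response genes were at 0.37 with 17beta-estradiol (percentile 96.3). Other lists stood as high, such as NRF2 genes with GW4046 at 0.55 (percentile 100) and, with sulforaphane, heat shock genes at 1.52 (percentile 100) and fatty acid synthesis genes at 0.67 (percentile 99.3), so a high percentile does not single out a pathway. The 11 glucocorticoid receptor genes with dexamethasone had a median of -0.25 (percentile 0.64).

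Each of the 29 chemicals was then tested for a trend over its 6 doses with edgeR, and values are fitted log2 changes at 33.3 µM with their SE unless stated (6 treated and 9 DMSO libraries per chemical). At an adjusted p under 0.05, 17 chemicals had 1 or more called probes and 6 had more than 10. Dithiopyr had 312 (123 higher, 189 lower), cyproconazole 113 (84 and 29), PFOA 98 (84 and 14), imazalil 50 (43 and 7), S-Bioallethrin 43 (28 and 15) and triadimefon 15 (14 and 1). With DMSO replicate 1 left out these became 1435, 989, 414, 1166, 324 and 106. Leaving out another single library below the highest dose could also move them, down to 156 for dithiopyr (without 3.7 µM), 63 for cyproconazole (without 1.2 µM), 34 for PFOA (without DMSO replicate 6), 0 for imazalil (without DMSO replicate 2), 9 for S-Bioallethrin (without 33.3 µM) and 7 for triadimefon (without 33.3 µM). Without the highest dose the counts were 8 for dithiopyr, 10 for cyproconazole, 24 for PFOA, 0 for imazalil in edgeR (366 at an unadjusted p under 0.05), 17 for S-Bioallethrin and 12 for triadimefon, while bisphenol A went from 0 to 625. In the same order, a dose score by rank gave 82, 2, 43, 0 in edgeR for imazalil (1991 at an unadjusted p under 0.05), 56 and 13, and the library score as a covariate 206, 312, 138, 4, 111 and 27. The other 11 chemicals with calls had 1 to 7. In edgeR 12 chemicals had 0: acetochlor, alachlor, bisphenol A, cyclanilide, DEHP, dichlobenil, dimethenamid, etoxazole, isoxaflutole, PFOS, simazine and triclosan. They had 232 to 2420 probes at an unadjusted p under 0.05, and DESeq2 called 0 to 188. Leaving out DMSO replicate 1, 24 chemicals had calls and 5 had 0. All trends share the 9 DMSO libraries, so counts over chemicals are not independent of each other.

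Genes of fatty acid oxidation that are induced through PPARα rose with PFOA and S-Bioallethrin, and a few of them with dithiopyr. Acot1 rose by 8.51 ± 0.94 with PFOA, 7.13 ± 1.18 with dithiopyr and 5.84 ± 0.70 with S-Bioallethrin (largest adjusted p 0.0073). It was close to absent in DMSO, at 0.331 ± 0.30 CPM (SD, n = 9), and reached 158 in the PFOA library at 100 µM and 26.7 in that of S-Bioallethrin. With dithiopyr the course was not steady, Acot1 being at 26.8 CPM at 11.1 µM and 9.51 at 33.3 µM. Ehhadh rose by 5.28 ± 0.52 with PFOA and 4.44 ± 0.43 with S-Bioallethrin, and Cyp4a1, a fatty acid hydroxylase, by 3.62 ± 0.33 with PFOA (largest adjusted p 0.000237). Pdk4 rose in all 3, by 3.60 ± 0.56 with dithiopyr, 3.47 ± 0.46 with PFOA and 2.30 ± 0.36 with S-Bioallethrin. Of the 26 measured list members, 13 rose with PFOA, 10 with S-Bioallethrin and 4 with dithiopyr, or 23, 15 and 9 adjusted over the list alone. As a set (camera) the list rose with PFOA (adjusted p = 3.04e-40), S-Bioallethrin (adjusted p = 1.8e-51) and dithiopyr (adjusted p = 0.000132), the last with adjusted p = 0.386 with an estimated correlation. It also rose as a set with bensulide, cyclanilide and DEHP, though at adjusted p = 0.199 to 0.386 with an estimated correlation over the 4 lost calls, and bensulide's call ended without DMSO replicate 1 (adjusted p = 0.0535). Pdk4 with S-Bioallethrin lost its call without the library at 33.3 µM, or the highest dose (adjusted p up to 0.0637, the change then at 2.05 to 2.49).

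In the opposite direction, fatty acid oxidation genes fell with 12 chemicals as a set (16 without DMSO replicate 1), 8 of which held with an estimated correlation (the other 4 at adjusted p = 0.103 to 0.286 with an estimated correlation). With cyproconazole the fatty acid transporter Cd36 was at -3.57 ± 0.38 and Cpt1a, which carries fatty acids into mitochondria, at -2.23 ± 0.43 (largest adjusted p 0.0183). In all, 4 of the 26 members fell with cyproconazole, 16 adjusted over the list alone (set adjusted p = 9.36e-09). Cd36 also fell with oxadiazon, by 1.64 ± 0.23 (adjusted p = 0.0256). Cpt1a with cyproconazole lost its call without DMSO replicate 4, or the highest dose (adjusted p up to 0.36, the change then at -2.17 to -1.82). Cd36 with oxadiazon lost its call without DMSO replicate 4 or 6, or the library at 0.4 or 3.7 µM, or the highest dose (adjusted p up to 0.259, the change then at -1.67 to -1.44). The call of Cpt1a (-2.21, adjusted p = 0.0562) with cyproconazole ended with a dose score by rank.

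Xenobiotic metabolism genes induced through CAR and PXR rose with several azole fungicides and with other chemicals. Cyp3a23/3a1, a steroid and drug hydroxylase, rose by 3.16 ± 0.43 with tetraconazole, 3.15 ± 0.48 with flusilazole and 2.85 ± 0.47 with triadimefon (largest adjusted p 0.0279). In CPM it was 19.5 ± 8.04 in DMSO (SD, n = 9), 159 in the tetraconazole library at 33.3 µM and 216 in the dexamethasone library. The glucuronidation gene Ugt2b1 rose by 3.26 ± 0.37 with flusilazole, 2.96 ± 0.30 with tetraconazole, 2.95 ± 0.37 with triadimefon, 2.62 ± 0.39 with triflumizole, 2.20 ± 0.29 with hexaconazole and 1.71 ± 0.21 with cyprodinil (largest adjusted p 0.0194). Cyp2b2 rose by 3.80 ± 0.54 with cyprodinil, 3.56 ± 0.73 with PFOA and 3.14 ± 0.62 with S-Bioallethrin (largest adjusted p 0.0414). Ugt2b10 was the single called probe of bensulide, at 2.53 ± 0.34 (adjusted p = 0.0213). Once DMSO replicate 1 was left out, Cyp2b2 passed with 14 chemicals in place of 3, Cyp3a23/3a1 with 12 in place of 3 and Cyp3a1 with 9 in place of 2. With tetraconazole 3 of the 18 list members rose, or 9 adjusted over the list alone. As a set the list rose with 14 chemicals (bensulide, carbaryl, cyprodinil, dichlobenil, fludioxonil, flusilazole, hexaconazole, isoxaflutole, oxadiazon, PFOS, S-Bioallethrin, tetraconazole, triadimefon and triflumizole), 11 of which held with an estimated correlation (the other 3 at adjusted p = 0.0779 to 0.252 with an estimated correlation). Cyp3a23/3a1 with tetraconazole lost its call without the highest dose (adjusted p up to 0.276, the change then at 3.47). Cyp3a23/3a1 with flusilazole lost its call without the library at 0.14, 0.4, 1.2, 3.7 or 11.1 µM, or the highest dose (adjusted p up to 0.165, the change then at 2.67 to 3.76). Cyp3a23/3a1 with triadimefon lost its call without DMSO replicate 7, 8 or 9, or the library at 0.4 or 33.3 µM (adjusted p up to 0.192, the change then at 2.35 to 2.95). Ugt2b1 with triflumizole lost its call without the library at 11.1 µM, or the highest dose (adjusted p up to 0.94, the change then at 2.34 to 2.72). Ugt2b1 with hexaconazole lost its call without the library at 11.1 µM, or the highest dose (adjusted p up to 0.765, the change then at 2.17 to 2.24). Ugt2b1 with cyprodinil lost its call without the highest dose (adjusted p up to 0.459, the change then at 1.55). Cyp2b2 with cyprodinil lost its call without DMSO replicate 5, or the highest dose (adjusted p up to 1, the change then at 3.25 to 3.74). Cyp2b2 with PFOA lost its call without DMSO replicate 4, 5 or 6, or the library at 0.4, 1.2, 3.7 or 33.3 µM (adjusted p up to 0.0945, the change then at 2.81 to 3.80). Cyp2b2 with S-Bioallethrin lost its call without DMSO replicate 4, 5 or 6, or the library at 0.4, 1.2, 3.7, 11.1 or 33.3 µM, or the highest dose (adjusted p up to 0.754, the change then at 1.85 to 3.44). Ugt2b10 with bensulide lost its call without the library at 0.14, 0.4 or 11.1 µM, or the highest dose (adjusted p up to 0.865, the change then at 1.64 to 2.59). The calls of Cyp3a23/3a1 (2.81, adjusted p = 0.142) with flusilazole, Ugt2b1 (2.22, adjusted p = 0.134) with triflumizole, Ugt2b1 (1.90, adjusted p = 0.18) with hexaconazole, Cyp2b2 (3.68, adjusted p = 0.0624) with PFOA, Cyp2b2 (3.27, adjusted p = 0.0798) with S-Bioallethrin and Ugt2b10 (2.13, adjusted p = 0.229) with bensulide ended with a dose score by rank. The call of Ugt2b10 (2.65, adjusted p = 0.0606) with bensulide ended with the library score. The calls of Cyp2b2 (2.77, adjusted p = 0.171) with cyprodinil, Cyp2b2 (2.44, adjusted p = 0.0543) with PFOA and Cyp2b2 (1.93, adjusted p = 0.163) with S-Bioallethrin ended without the plate term. The call of Cyp2b2 (3.13, adjusted p = 0.0526) with S-Bioallethrin ended with DESeq2's size factors.

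Cyp1a1, the classical target of the aryl hydrocarbon receptor (AhR), rose with 5 chemicals. Its change was 5.78 ± 0.54 with tetraconazole, 4.59 ± 0.60 with fludioxonil, 4.54 ± 0.74 with triflumizole, 4.08 ± 0.63 with hexaconazole and 3.87 ± 0.51 with carbaryl (largest adjusted p 0.0433). It was at 1.14 ± 1.12 CPM in DMSO (SD, n = 9) and at 34.5 and 152 in the highest doses of tetraconazole and fludioxonil. Without DMSO replicate 1, where it had 0 counts, simazine at 3.30 ± 0.64 (adjusted p = 0.0488) and cyprodinil at 2.43 ± 0.45 (adjusted p = 0.0369) passed too. Cyp1a2, another AhR target, was not called with any chemical by edgeR with all DMSO libraries, being highest with tetraconazole, at 1.29 ± 0.31 (adjusted p = 0.462). It was called lower with dithiopyr when DMSO replicate 1 was left out, at -1.55 ± 0.39 (adjusted p = 0.017). The list has 3 measured members and rose as a set with 14 chemicals, of which 5 held with an estimated correlation (the other 9 at adjusted p = 0.0829 to 0.245 with an estimated correlation). It rose with 16 when DMSO replicate 1 was left out, while the calls of dichlobenil, oxadiazon and PFOS ended (adjusted p = 0.0516 to 0.0799). Cyp1a1 with tetraconazole lost its call without the highest dose (adjusted p up to 0.052, the change then at 5.84). Cyp1a1 with fludioxonil lost its call without DMSO replicate 6, or the highest dose (adjusted p up to 1, the change then at 2.72 to 4.57). Cyp1a1 with triflumizole lost its call without DMSO replicate 2 or 3, or the library at 1.2, 3.7 or 11.1 µM, or the highest dose (adjusted p up to 0.94, the change then at 4.38 to 4.62). Cyp1a1 with hexaconazole lost its call without DMSO replicate 2 or 3, or the library at 0.14, 0.4, 1.2, 3.7 or 11.1 µM, or the highest dose (adjusted p up to 0.886, the change then at 3.98 to 4.33). Cyp1a1 with carbaryl lost its call without DMSO replicate 6, or the library at 33.3 µM, or the highest dose (adjusted p up to 0.842, the change then at 3.83 to 3.97). The call of Cyp1a1 (4.16, adjusted p = 0.0862) with hexaconazole ended with a dose score by rank. The call of Cyp1a1 (4.12, adjusted p = 0.0872) with fludioxonil ended with the library score. The call of Cyp1a1 (3.07, adjusted p = 0.467) with hexaconazole ended without the plate term.

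Oxidative stress and glutathione genes induced through NRF2 rose as a set with 20 chemicals, of which 7 held with an estimated correlation (the other 13 at adjusted p = 0.0571 to 0.304 with an estimated correlation). With dithiopyr Gstp1, a glutathione transferase, rose by 3.53 ± 0.59, Srxn1, which repairs oxidised peroxiredoxins, by 2.14 ± 0.40 and the epoxide hydrolase gene Ephx1 by 1.84 ± 0.33 (largest adjusted p 0.0153). With triflumizole the quinone reductase gene Nqo1 rose by 2.10 ± 0.32 and Gclc, which starts glutathione synthesis, by 1.61 ± 0.24 (largest adjusted p 0.0221). Of the 20 members 8 rose with dithiopyr and 2 with triflumizole, or 13 and 13 adjusted over the list alone. This list stood at a median of -1.32 in DMSO replicate 1 (members from -3.78 to 1.74), and without that library it rose with 21 chemicals. Gstp1, Srxn1 and Ephx1 with dithiopyr lost their calls without the highest dose (adjusted p up to 0.608, changes then at 3.30, 1.15 and 1.50). Nqo1 with triflumizole lost its call without DMSO replicate 2 or 3, or the library at 11.1 µM, or the highest dose (adjusted p up to 0.94, the change then at 1.74 to 2.14). Gclc with triflumizole lost its call without DMSO replicate 2, or the highest dose (adjusted p up to 0.94, the change then at 1.06 to 1.62). The calls of Nqo1 (1.85, adjusted p = 0.136) and Gclc (1.45, adjusted p = 0.115) with triflumizole ended with a dose score by rank.

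Integrated stress response genes rose with cyproconazole and, for some members, with imazalil. The transcription factor gene Ddit3 (CHOP) rose by 3.46 ± 0.69 with imazalil and 2.73 ± 0.43 with cyproconazole, and Atf3 by 2.73 ± 0.51 and 2.60 ± 0.43 (largest adjusted p 0.0473). Ppp1r15a, which restores translation, rose by 2.30 ± 0.32 with cyproconazole. With cyproconazole 5 of the 18 members rose, 8 adjusted over the list alone (set adjusted p = 3.12e-06). The set also rose with oxadiazon, PFOA and triadimefon, at adjusted p = 0.103 to 0.15 with an estimated correlation. It fell with ametryn and cyprodinil, and with 4 chemicals without DMSO replicate 1, ametryn being at adjusted p = 0.198 with an estimated correlation. Ddit3 with imazalil lost its call without DMSO replicate 2 or 3, or the library at 0.14, 0.4, 1.2 or 3.7 µM, or the highest dose (adjusted p up to 0.92, the change then at -1.26 to 3.58). Atf3 with imazalil lost its call without DMSO replicate 2 or 3, or the library at 0.4 or 1.2 µM, or the highest dose (adjusted p up to 0.98, the change then at -0.11 to 2.87). Ddit3, Atf3 and Ppp1r15a with cyproconazole lost their calls without the highest dose (adjusted p 0.918 to 1, changes then at 0.71, 0.24 and 0.74). The calls of Ddit3 (3.01, adjusted p = 0.156) and Atf3 (2.45, adjusted p = 0.145) with imazalil and Ddit3 (2.85, adjusted p = 0.0531), Atf3 (2.68, adjusted p = 0.0562) and Ppp1r15a (2.34, adjusted p = 0.0531) with cyproconazole ended with a dose score by rank. The calls of Ddit3 (2.88, adjusted p = 0.071) and Atf3 (2.43, adjusted p = 0.0729) with imazalil ended with the library score. The call of Atf3 (1.93, adjusted p = 0.0507) with imazalil ended with the score and without DMSO replicate 1. DESeq2 gave no adjusted p for Ddit3 (3.42) with imazalil. The trends of Ddit3 and Atf3 rest on the highest dose with both chemicals, being at -1.26 and -0.11 without it for imazalil. For cyproconazole that library, at 100 µM, was the shallowest of the 174 dose libraries (1340300 counts).

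Lipid synthesis genes rose with triadimefon. Srebf1, the regulator of fatty acid synthesis, rose by 1.73 ± 0.22, the fatty acid synthase gene Fasn by 1.27 ± 0.22 and the desaturase gene Fads1 by 1.23 ± 0.20 (largest adjusted p 0.0294), which made 3 of 12 members, 5 adjusted over the list alone (set adjusted p = 2.17e-15). The list fell as a set with 13 chemicals, 1 of which held with an estimated correlation (the others at adjusted p = 0.0548 to 0.304 with an estimated correlation). With dithiopyr Acly, which makes cytosolic acetyl-CoA, was at -1.99 ± 0.33 and Thrsp at -5.58 ± 1.23 (largest adjusted p 0.0286). Without DMSO replicate 1, which had 692 CPM of Thrsp against 83.1 ± 33.0 in the other DMSO libraries (SD, n = 8), the change of Thrsp was -3.38 ± 0.61. Cholesterol synthesis genes rose as a set with flusilazole, tetraconazole and triadimefon, triadimefon alone holding with an estimated correlation (the others at adjusted p = 0.052 to 0.0735 with an estimated correlation). They fell with 7 chemicals, or 11 without DMSO replicate 1, 2 of the 7 holding (the others at adjusted p = 0.0639 to 0.228 with an estimated correlation). Srebf1 with triadimefon lost its call without the highest dose (adjusted p up to 0.505, the change then at 1.07). Fasn with triadimefon lost its call without DMSO replicate 7, 8 or 9, or the library at 0.4, 1.2, 3.7 or 33.3 µM, or the highest dose (adjusted p up to 0.687, the change then at 1.15 to 1.33). Fads1 with triadimefon lost its call without DMSO replicate 7 or 9, or the library at 0.4, 1.2 or 33.3 µM, or the highest dose (adjusted p up to 0.194, the change then at 1.07 to 1.32). Acly with dithiopyr lost its call without the highest dose (adjusted p up to 0.562, the change then at -1.42). Thrsp with dithiopyr lost its call without the library at 3.7 or 11.1 µM, or the highest dose (adjusted p up to 0.608, the change then at -6.01 to -5.28). The calls of Fasn (1.31, adjusted p = 0.0653) and Fads1 (1.24, adjusted p = 0.0653) with triadimefon and Acly (-1.61, adjusted p = 0.0564) with dithiopyr ended with a dose score by rank. The calls of Fasn (1.02, adjusted p = 0.0563) with triadimefon and Thrsp (-4.40, adjusted p = 0.153) with dithiopyr ended without the plate term. The call of Fads1 (1.23, adjusted p = 0.0596) with triadimefon ended without a filter.

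Genes of hepatocyte identity fell with dithiopyr most widely. Cps1, the first enzyme of the urea cycle, fell by 4.01 ± 0.55 and Ambp, a secreted protein gene, by 1.35 ± 0.24 (largest adjusted p 0.0109). In all, 8 of 26 members fell, 18 adjusted over the list alone (set adjusted p = 4.71e-11). With triticonazole Cps1 was at -1.97 ± 0.30 (adjusted p = 0.0452). As a set the list fell with 11 chemicals, of which 5 held with an estimated correlation (the others at adjusted p = 0.0836 to 0.349 with an estimated correlation). Macrophage markers fell with 5 chemicals, 1 holding (the others at adjusted p = 0.0788 to 0.229 with an estimated correlation), stellate cell markers with imazalil (adjusted p = 0.124 with an estimated correlation) and endothelial markers with dimethenamid (adjusted p = 0.103 with an estimated correlation). Stellate cell markers fell with 4 chemicals without DMSO replicate 1, where the endothelial call of dimethenamid ended (adjusted p = 0.0566) and endothelial markers rose with etoxazole (adjusted p = 0.0358, but adjusted p = 0.197 with an estimated correlation). Cps1 and Ambp with dithiopyr lost their calls without the highest dose (adjusted p 0.0994 and 0.591, changes then at -2.83 and -1.18). Cps1 with triticonazole lost its call without DMSO replicate 4, 5 or 6, or the library at 0.4, 3.7 or 11.1 µM, or the highest dose (adjusted p up to 0.746, the change then at -2.04 to -1.55). The calls of Cps1 (-2.85, adjusted p = 0.0698) and Ambp (-1.08, adjusted p = 0.0745) with dithiopyr ended with a dose score by rank. The call of Cps1 (-1.98, adjusted p = 0.0566) with triticonazole ended with DESeq2's size factors.

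The other lists gave these results as sets over the 29 chemicals. Cell cycle genes fell with 9 chemicals, dimethenamid holding with an estimated correlation (the others at adjusted p = 0.095 to 0.308 with an estimated correlation), and rose with DEHP and dithiopyr (adjusted p = 0.195 to 0.503 with an estimated correlation). Glucocorticoid receptor genes rose with 8 chemicals and fell with DEHP, or rose with 5 and fell with 2 without DMSO replicate 1, where the rises of acetochlor, bensulide and hexaconazole ended (adjusted p = 0.0944 to 0.38 for the rises and 0.371 for the fall with an estimated correlation). Bile acid synthesis genes fell with 7, dichlobenil holding (the others at adjusted p = 0.052 to 0.154 with an estimated correlation). FXR genes fell with cyprodinil and oxadiazon (adjusted p = 0.294 to 0.315 with an estimated correlation), and with 6 chemicals without DMSO replicate 1. Genes of the unfolded protein response fell with 4, DEHP holding (the others at adjusted p = 0.103 to 0.252 with an estimated correlation). Heat shock genes rose with cyclanilide and dithiopyr (adjusted p = 0.145 to 0.231 with an estimated correlation), and p53 genes with cyproconazole and triticonazole (adjusted p = 0.0501 to 0.246 with an estimated correlation). Inflammation genes fell with dithiopyr and triflumizole (adjusted p = 0.268 to 0.276 with an estimated correlation). The p53 rises and the inflammation falls came to 3 each without DMSO replicate 1. Oestrogen response genes were called with no chemical by camera with all DMSO libraries. Leaving out DMSO replicate 1, they rose with isoxaflutole, heat shock genes fell with dimethenamid and inflammation genes rose with tetraconazole (adjusted p = 0.00332 to 0.0175, but adjusted p = 0.146 to 0.197 with an estimated correlation). Among single genes, Pck1, an enzyme gene of glucose synthesis, rose by 2.46 ± 0.33 with ametryn (adjusted p = 0.0139), and the muscle protein gene Csrp3 by 2.48 ± 0.41 with oxadiazon and 2.22 ± 0.34 with triticonazole (largest adjusted p 0.0452). Pck1 with ametryn lost its call without the library at 0.14 or 0.4 µM, or the highest dose (adjusted p up to 0.611, the change then at 1.27 to 2.45). Csrp3 with oxadiazon lost its call without DMSO replicate 4 or 6, or the library at 0.4, 1.2 or 3.7 µM, or the highest dose (adjusted p up to 1, the change then at 0.80 to 2.63). Csrp3 with triticonazole lost its call without DMSO replicate 4, 5 or 6, or the library at 0.4, 3.7 or 11.1 µM, or the highest dose (adjusted p up to 0.963, the change then at 1.28 to 2.30). The calls of Pck1 (2.16, adjusted p = 0.0847) with ametryn, Csrp3 (2.51, adjusted p = 0.249) with oxadiazon and Csrp3 (2.38, adjusted p = 0.0588) with triticonazole ended with a dose score by rank. The calls of Csrp3 (2.49, adjusted p = 0.0518) with oxadiazon and Csrp3 (2.21, adjusted p = 0.0566) with triticonazole ended with DESeq2's size factors.

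**Figure D2:**
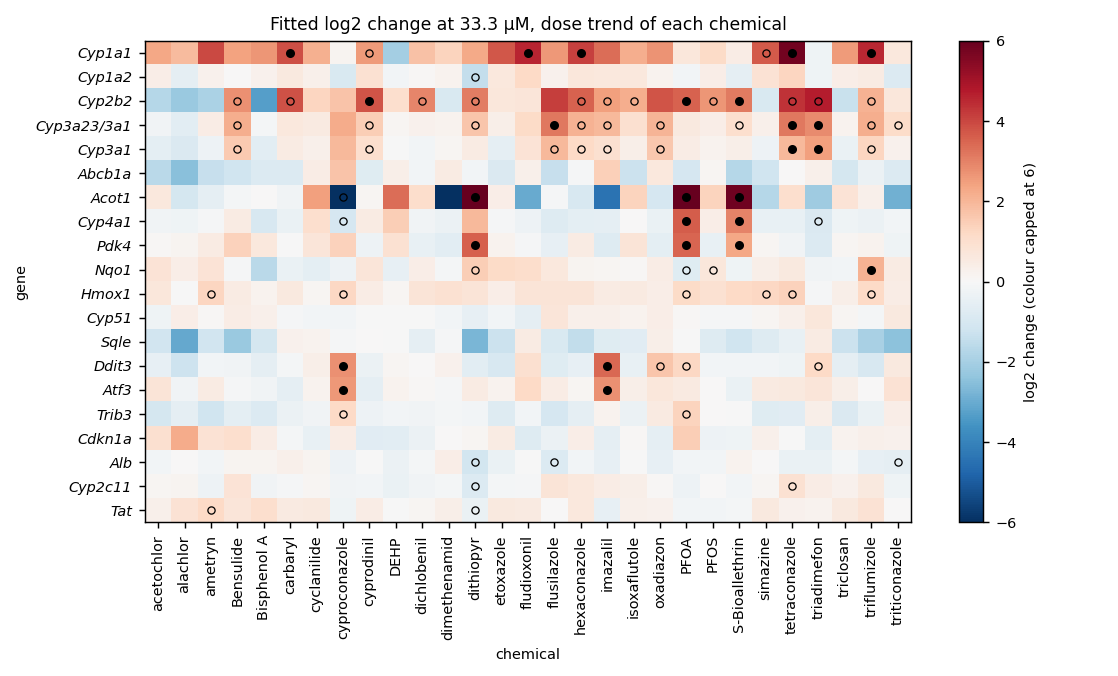
Fitted log2 change at 33.3 µM of genes fixed in advance (vertical axis) for each of the 29 chemicals (horizontal axis), with colour capped at 6. A filled dot marks an adjusted p under 0.05 with all DMSO libraries and an open dot one reached only without DMSO replicate 1; Cyp1a1 has 5 filled dots, and Cyp2b2 has 3 filled and 11 open dots.

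**Figure D3:**
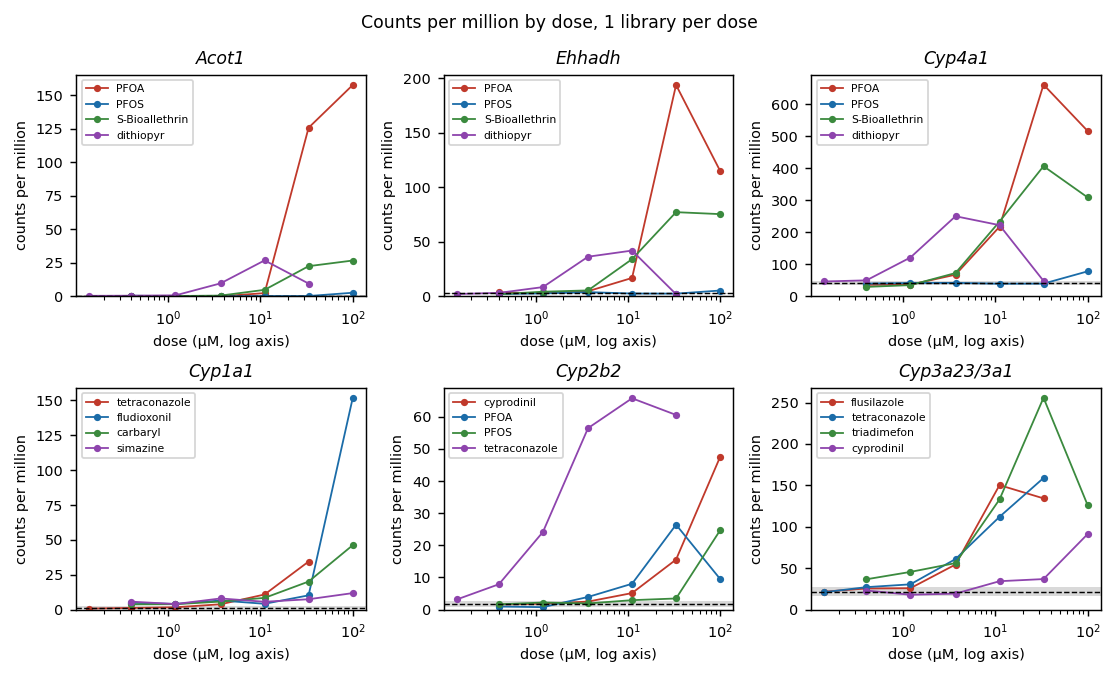
CPM of 6 genes against dose in µM on a log axis, 1 library per dose, for 4 chemicals in each panel. The dashed line and grey band are the mean and SD of DMSO replicates 2 to 9; Acot1 with PFOA goes from 2.38 at 11.1 µM to 126 at 33.3 µM.

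The 8 azole fungicides (48 libraries) share a triazole or imidazole ring, and their mean trend was tested. With all DMSO libraries, Cyp1a1 was called singly with hexaconazole, tetraconazole and triflumizole among them, and Cyp2b2 with no azole. The means below thus do not show a change with each azole. Cyp2b2 rose by 3.15 ± 0.68, Ugt2b1 by 2.42 ± 0.28, Cyp3a23/3a1 by 2.39 ± 0.28, Ugt2b10 by 2.37 ± 0.27 and Cyp1a1 by 2.08 ± 0.46 (largest adjusted p 0.00104). Below these came Cyp3a1 at 1.71 ± 0.23, Cyp2c24 at 1.61 ± 0.26, the glutathione transferase genes Gsta50.81 at 1.47 ± 0.12 and Gsta2 at 1.39 ± 0.17, and Oxct1, of ketone body use, at 1.39 ± 0.26 (largest adjusted p 0.000132). Among falls that held their call without DMSO replicate 1, chosen after their values were seen, the phosphate transporter gene Slc34a2 fell by 1.94 ± 0.17 (adjusted p = 6.55e-12). Fatty acid oxidation genes fell, 17 of 26 (17 down and 1 up adjusted over the list alone), among them Acadl at -0.46 ± 0.06, Hadha at -0.47 ± 0.07 and Vnn1 at -1.31 ± 0.20 (set adjusted p = 9.05e-12). NRF2 genes rose, 12 of 20 (14 adjusted over the list alone), such as Srxn1 at 1.12 ± 0.15 and Hmox1 at 0.72 ± 0.14 (set adjusted p = 5.66e-12). The calls of Oxct1 (0.39, adjusted p = 0.68), Hadha (-0.31, adjusted p = 0.0605), Srxn1 (0.53, adjusted p = 0.0825) and Hmox1 (0.71, adjusted p = 0.0604) with the azoles ended without the highest doses.

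Of the 18 CAR and PXR genes 10 rose with the azoles and 3 fell (10 and 4 adjusted over the list alone), the falls being Aldh1a1 at -1.18 ± 0.21, Cyp3a9 at -0.49 ± 0.12 and Ugt1a1 at -1.37 ± 0.46, the last at 0.40 without DMSO replicate 1. As a set they rose (adjusted p = 1.56e-06, but adjusted p = 0.177 with an estimated correlation). Hepatocyte genes fell, 13 of 26 against 2 rises (17 and 2 adjusted over the list alone), among them the transferrin gene Tf at -1.08 ± 0.19, while Hpd rose by 0.34 ± 0.09 and Cyp2c11 by 0.33 ± 0.12 (set adjusted p = 2.54e-05, but adjusted p = 0.189 with an estimated correlation). Cholesterol synthesis genes rose, 4 of 21 (4 adjusted over the list alone), led by Insig1 at 0.94 ± 0.16 (set adjusted p = 0.0308, but adjusted p = 0.358 with an estimated correlation). In edgeR 2139 of 11055 probes were called for the class, 743 higher and 1396 lower. Without DMSO replicate 1 the count was 2891 (1286 and 1605), without imazalil 1165, and without the highest dose of each chemical 142. The 10 largest falls with all DMSO libraries depended on replicate 1: Pfdn1 at -4.51, Ccng1 at -4.42 and P2rx4 at -3.67 became 0.07, 0.78 and -0.16 without it, 1 of the 10 was still called lower, and 2, Ccng1 and Timm9, were called higher. Ugt1a1 with the azoles lost its call without DMSO replicate 1, or cyproconazole (adjusted p up to 0.0532, the change then at -1.43 to 0.40). Hpd with the azoles lost its call without imazalil (adjusted p up to 0.0532, the change then at 0.28). Cyp2c11 with the azoles lost its call without DMSO replicate 4, 5, 6, 7, 8 or 9, or flusilazole, hexaconazole, tetraconazole, triadimefon, imazalil or triflumizole (adjusted p up to 0.153, the change then at 0.28 to 0.34). The call of Ugt1a1 (-0.88, adjusted p = 0.0621) with the azoles ended with the library score. The calls of Ugt1a1 (0.35, adjusted p = 0.0698) and Cyp2c11 (0.26, adjusted p = 0.0511) with the azoles ended with the score and without DMSO replicate 1. The call of Cyp2c11 with the azoles ended without the plate term (0.29, adjusted p = 0.0942) or a filter (0.34, adjusted p = 0.0705). DESeq2 gave no adjusted p for Ugt1a1 (-1.48) with the azoles. The calls of Aldh1a1 (-0.53, adjusted p = 0.138), Cyp3a9 (-0.25, adjusted p = 0.407), Ugt1a1 (-2.37, adjusted p = 0.0811), Tf (-0.86, adjusted p = 0.0605), Hpd (0.31, adjusted p = 0.275) and Insig1 (0.33, adjusted p = 0.504) with the azoles ended without the highest doses.

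The imidazoles imazalil and triflumizole were compared with the 3 triazoles of the same plate and doses (flusilazole, hexaconazole and tetraconazole), a difference in the ring that carries the azole nitrogens. The single probe that passed was Spata2L, at -0.63 ± 0.11 for imidazoles minus triazoles (adjusted p = 0.0357). For Cyp2b2 the difference was -2.76 with a 95% interval from -4.68 to -0.85 (adjusted p = 0.592). Cholesterol synthesis genes were lower in imidazoles as a set (adjusted p = 1.35e-05), although 0 of the 21 passed singly in edgeR, 0 also adjusted over the list alone. NRF2 genes were higher as a set (adjusted p = 3.28e-05, but adjusted p = 0.0611 with an estimated correlation), with 2 of 20 members, Gstp1 at 1.35 ± 0.40 and Srxn1 at 0.93 ± 0.29, passing adjusted over the list alone, and Srxn1 was at -0.28 without the highest doses. CAR and PXR genes were lower as a set (adjusted p = 0.000162, but adjusted p = 0.0889 with an estimated correlation). Hepatocyte, inflammation and fatty acid synthesis genes were lower as well, at adjusted p = 0.324, 0.115 and 0.152 with an estimated correlation. The count was 39 without DMSO replicate 1, with 633 probes at an unadjusted p under 0.05 and 14 called by DESeq2 on all libraries. The median half-width of the 95% interval was 0.58, and 7472 of 11055 probes had an interval within 1 log2 unit of 0. The call of Spata2L ended with a dose score by rank (-0.51, adjusted p = 0.104) and without a filter (-0.64, adjusted p = 0.137). It also ended without the highest doses (-0.58, adjusted p = 1).

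PFOA and PFOS are perfluorinated C8 acids, PFOA with a carboxylate and PFOS with a sulfonate end group. Their mean trend raised Acot1 by 5.80 ± 1.10, Cyp2b2 by 3.24 ± 0.52, Ehhadh by 2.96 ± 0.41, Cyp4a1 by 2.10 ± 0.23 and Pex11a, a peroxisome division gene, by 2.01 ± 0.32 (largest adjusted p 0.0158). The bile acid transporter gene Slc10a2 was at -1.33 ± 0.27 (adjusted p = 0.0262). Of the 26 PPARα genes 6 rose (21 up and 1 down adjusted over the list alone, set adjusted p = 5.58e-33). This mean does not show that both acids raised them. In the trends of single chemicals the set rose with PFOA and was not called higher with PFOS. PFOS had 0 called probes in edgeR (252 at an unadjusted p under 0.05, 7 called by DESeq2). CAR and PXR genes rose as a set (adjusted p = 0.239 with an estimated correlation), as did NRF2 genes (adjusted p = 0.228 with an estimated correlation) and stress response genes (adjusted p = 0.225 with an estimated correlation), while hepatocyte genes fell (adjusted p = 0.056 with an estimated correlation). The class had 32 called probes (21 higher and 11 lower), 166 without DMSO replicate 1, 188 without the plate term and 6 without the highest doses. Slc10a2 with the perfluorinated acids lost its call without DMSO replicate 4, 5 or 6 (adjusted p up to 0.0884, the change then at -1.34 to -1.18). The call of Acot1 (6.67, adjusted p = 0.0738) with the perfluorinated acids ended with a dose score by rank. The calls of Acot1 (5.15, adjusted p = 1), Cyp2b2 (2.91, adjusted p = 0.185), Pex11a (1.23, adjusted p = 0.874) and Slc10a2 (-1.30, adjusted p = 0.532) with the perfluorinated acids ended without the highest doses.

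At the same 6 doses from 0.4 to 100 µM, PPARα genes were higher with PFOA than with PFOS. Against the DMSO libraries of plate 2, the median of the list with PFOS ran from -0.412 (3.7 µM) to 0.113 (100 µM). With PFOA it ran from -0.214 (0.4 µM) to 1.82 (33.3 µM). The difference PFOA minus PFOS was 6.29 ± 0.97 for Acot1, 4.73 ± 0.56 for Ehhadh, 3.42 ± 0.52 for Pdk4 and 3.11 ± 0.34 for Cyp4a1 (largest adjusted p 0.00112). In the libraries at 33.3 µM Cyp4a1 was at 662 CPM with PFOA and 39.7 with PFOS, against 41.5 ± 6.94 in DMSO (SD, n = 9). Slc34a2 was also higher with PFOA, at 3.36 ± 0.43. Nqo1 was lower with PFOA, at -1.60 ± 0.20, and so was the early response gene Egr1, at -1.48 ± 0.31 (largest adjusted p 0.0211). Of the 26 PPARα genes 16 were higher with PFOA (23 adjusted over the list alone, set adjusted p = 2.86e-44). NRF2 genes were lower as a set (adjusted p = 5.45e-06), 1 of 20 singly and 7 adjusted over the list alone, and so were cell cycle genes (adjusted p = 2.11e-05). Stress response genes were higher (adjusted p = 0.00133, but adjusted p = 0.0889 with an estimated correlation), with Ddit4 at 2.18 ± 0.38 and Vldlr at 2.23 ± 0.54, and macrophage markers lower (adjusted p = 0.156 with an estimated correlation). In edgeR 117 probes were called (89 higher and 28 lower with PFOA), 445 without DMSO replicate 1 and 58 without the 100 µM libraries. The call of Vldlr (2.16, adjusted p = 0.0525) with PFOA minus PFOS ended with a dose score by rank. The call of Vldlr (2.21, adjusted p = 0.0534) with PFOA minus PFOS ended without a filter. The calls of Egr1 (-1.15, adjusted p = 0.185), Ddit4 (1.60, adjusted p = 0.229) and Vldlr (1.86, adjusted p = 0.401) with PFOA minus PFOS ended without the highest doses.

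The mean trend of the s-triazine herbicides ametryn and simazine raised Cyp1a1 by 3.48 ± 0.70, Pck1 by 1.70 ± 0.22, the metallothionein gene Mt2A by 1.67 ± 0.39 and Adm, a vasodilator peptide gene, by 1.94 ± 0.39 (largest adjusted p 0.044). Rem1, a small GTPase gene, fell by 3.95 ± 0.48, the cyclin gene Ccna2 by 2.46 ± 0.39 and the intestinal fatty acid binding protein gene Fabp2 by 2.33 ± 0.49 (largest adjusted p 0.0287), Fabp2 being at -1.47 without DMSO replicate 1. Acaca, which starts fatty acid synthesis, fell by 1.91 ± 0.33. As sets, glucocorticoid receptor genes rose (2 of 11, or 5 up and 2 down adjusted over the list alone), as did NRF2 genes (2 of 20, or 5) and AhR genes (1 of 3, or 1). Fatty acid synthesis genes fell (2 of 12, or 6 adjusted over the list alone), as did cell cycle genes (1 of 15, or 2). All 5 set calls were lost, at adjusted p = 0.056 to 0.218 with an estimated correlation. The class had 107 called probes (22 higher and 85 lower), 310 without DMSO replicate 1, 34 without DMSO replicate 2 and 0 in edgeR without the highest doses (1497 at an unadjusted p under 0.05, DESeq2 not run there). Cyp1a1 with the triazines lost its call without DMSO replicate 2 or 3 (adjusted p up to 0.0567, the change then at 3.31 to 3.46). Mt2A with the triazines lost its call without DMSO replicate 2, 3, 4, 6, 7, 8 or 9 (adjusted p up to 0.0807, the change then at 1.51 to 1.70). Adm with the triazines lost its call without DMSO replicate 2 or 3 (adjusted p up to 0.058, the change then at 1.86 to 1.88). The calls of Adm (1.41, adjusted p = 0.0562) and Fabp2 (-1.76, adjusted p = 0.125) with the triazines ended without the plate term. The calls of Cyp1a1 (3.69, adjusted p = 0.283), Pck1 (1.01, adjusted p = 0.267), Mt2A (2.19, adjusted p = 0.267), Adm (2.48, adjusted p = 0.259), Rem1 (-3.80, adjusted p = 0.0905), Ccna2 (-1.93, adjusted p = 0.267), Fabp2 (-2.58, adjusted p = 0.267) and Acaca (-1.81, adjusted p = 0.267) with the triazines ended without the highest doses.

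Among other differences, ametryn carries a methylthio group on the ring where simazine carries chlorine. They were compared at the 5 shared doses from 0.4 to 33.3 µM. Simazine's libraries at 100, 33.3 and 11.1 µM were on plate 1 and those at 3.7, 1.2 and 0.4 µM on plate 2, so its dose runs along with plate, while ametryn was on plate 1 throughout. The plate term thus bears on simazine's trend, on the class trend above and on this difference. The difference ametryn minus simazine was 0.71 for Cyp1a1, with a 95% interval from -1.79 to 3.22. Macrophage markers were lower as a set (adjusted p = 0.00037) and so were stellate cell markers (adjusted p = 0.00133), of which the smooth muscle protein gene Tagln, at -2.63 ± 0.55, passed adjusted over the list alone. Glucocorticoid receptor and NRF2 genes were higher and stress response, inflammation and fatty acid synthesis genes lower as sets, all lost at adjusted p = 0.0676 to 0.304 with an estimated correlation. In edgeR 0 probes were called (272 at an unadjusted p under 0.05, 7 called by DESeq2), and 1 without DMSO replicate 1. The median half-width of the 95% intervals was 1.12, and 2232 of 11055 probes had an interval within 1 log2 unit of 0. The missing calls thus do not show that the compounds act alike.

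The chloroacetamide herbicides acetochlor, alachlor and dimethenamid showed no probe past the threshold as a class in edgeR (0 called, 1698 at an unadjusted p under 0.05, 29 called by DESeq2). Without DMSO replicate 1 there were 10, among them, chosen after their values were seen, Gstp1 at 1.13 ± 0.22 and Rem1 at -1.67 ± 0.32 (largest adjusted p 0.0306). As sets, NRF2 genes (adjusted p = 0.000922) and glucocorticoid receptor genes (adjusted p = 0.00797) rose, and fatty acid synthesis (adjusted p = 0.000693), macrophage (adjusted p = 0.00389), cholesterol synthesis (adjusted p = 0.0131) and cell cycle genes (adjusted p = 0.0269) fell. All 6 were lost at adjusted p = 0.056 to 0.264 with an estimated correlation. Adjusted over the list alone, 7 of 12 fatty acid synthesis genes fell, and 4 of 13 macrophage markers, C1qc being at -1.08 ± 0.28, or -0.71 without DMSO replicate 1. Acetochlor and alachlor, which differ in alkyl groups on the ring and in the ether chain, were compared over the same 6 doses. For acetochlor minus alachlor Cyp1a1 was at 0.81 (95% interval -1.28 to 2.89), Cyp2b2 at 0.21 (-2.55 to 2.97) and Cyp3a1 at 0.27 (-0.36 to 0.90). In edgeR 0 probes were called (680 at an unadjusted p under 0.05, 0 by DESeq2), with a median half-width of 1.05.

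A lowest active dose was the dose from which that library and every higher one had more called probes than any DMSO library. Treated libraries were tested singly against DMSO, and each DMSO library against the others. With replicate 1 among the controls, which itself had 5595 calls, 0 of 29 chemicals reached one, and 0 when a fold of at least 2 was also asked (edgeR; other tools and unadjusted counts were not run through this rule). Without DMSO replicate 1, where DMSO replicate 5 set the bar with 1467 calls, 3 chemicals had one: cyproconazole at 100 µM with 3305 called probes, imazalil at 33.3 µM with 3270 and PFOA at 100 µM with 4189. For each of these it was the highest dose given. Replicate 5 was among the controls of treated libraries, but not its own. The cyproconazole library at 100 µM was the shallowest of the 174 dose libraries, with 1340300 counts, and the PFOA library at 100 µM held 2304919 counts and had the highest library score, 1.72. For these 2 libraries an effect of dose was not separated from depth, nor for PFOA from that score. The imazalil library held 6614172 counts and had a score of -0.57.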

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

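In this part the tests of depth and of a mislabelled library for DMSO replicate 1, those of the library score, and those of depth and the score for PFOA and PFOS were chosen only after the result was seen.

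DMSO replicate 1 lay far from the other 8 DMSO libraries. Its median correlation with them was 0.735, where the nearest other library had 0.883, and it had 5595 probes called against the others where each of the others had 0 in edgeR (replicate 5 had 1467 once replicate 1 was left out). In CPM its value lay apart from the nearest library for Cyp2b2 (8.54, nearest 3.26), Nqo1 (27.1, nearest 56.4), Cyp51 (106.5, nearest 209), Sqle (570.1, nearest 228), Ddit3 (117, nearest 79.4), Cyp2c11 (85.4, nearest 447) and Tat (6.36, nearest 70.0). Other DMSO libraries lay apart for Acot1 (replicate 6, 1.03, nearest 0.376) and Cdkn1a (replicate 5, 19.5, nearest 7.75). Of 24 measures of the 9 libraries, 11 had such a value, 9 of them in replicate 1. Chance gives about 1 in 20, and the measures share libraries.

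The total of 5500637 counts in replicate 1 lies inside the range of the other 8, which argues against depth. Marker medians against the other 8 were -0.41 for macrophages, 0.33 for endothelial cells and -0.20 for stellate cells, but a bound of 0 set beforehand was too weak, since members went both ways (from -1.47 to 2.35, -2.05 to 1.63 and -2.19 to 1.60). The most abundant of these markers, Vim, was at 16.5 CPM against 142 ± 21.4 (SD, n = 8), while the macrophage marker C1qc was at 28.0 against 15.5 ± 3.16. The deviations of replicate 1 correlated at most at 0.456 with those of 87 treated libraries of plate 1 (acetochlor at 11.1 µM). The same value for other DMSO libraries ran from 0.31 to 0.931, and each chemical and dose has 1 library. The value therefore cannot decide whether replicate 1 is a mislabelled library of that plate. RNA of other cell types, a mislabelled library of this or another plate, a failed well and a handling difference stay open. No biological explanation was tested.

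Libraries of many chemicals and doses departed along the direction of DMSO replicate 5. Across the 29 chemicals the median Spearman correlation of the library score with dose was -0.0286 (14 above 0, range -0.771 to 0.829), which argues against a common response to the chemicals. Over the treated libraries its correlation with total count was -0.211 (permutation p = 0.0044), and -0.0379, -0.152 and -0.367 within plates 1, 2 and 3, so depth goes with a small part of it at most. Base composition was not tested, since probe sequences were not at hand, and no biological explanation was tested.

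The trends of PFOA and PFOS differed, with 117 called probes, the PPARα list having a median difference of 1.48. Depth differed by more than 1.5 times at 0 of the 6 doses (highest ratio 1.15), with the library score as a covariate the median was 1.45, and with 1 dose left out it was 1.3 at the lowest (33.3 µM). These argue against depth, the score or 1 mislabelled library as the whole cause. A difference in how the compounds act through PPARα may remain, as a hypothesis found and tested on the same data. Imidazoles and triazoles differed in 1 called probe.

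Counts were also set against those after reassigning the same libraries to other places in the design. The real count was the highest for the azoles (1 of 25 arrangements reached the real count of 2139, highest other 78), the perfluorinated acids (1 of 25, real 32, highest other 0) and PFOA minus PFOS (1 of 32, real 117, highest other 88). That is the smallest share so few arrangements can give, and it was not adjusted over the comparisons. It argues against chance for these fits without excluding it. For the triazines chance stays open (2 of 25, real 107, highest other 2356). Where the real count is 0, any arrangement reaches it, so nothing follows about chance for the plates (100 of 100, real 0, highest other 0), the chloroacetamides (25 of 25, real 0, highest other 1234), acetochlor minus alachlor (32 of 32, real 0, highest other 0) and ametryn minus simazine (16 of 16, real 0, highest other 0). The 1234 and 2356 arose with DMSO replicate 1 placed at 33.3 µM, which points to a structure of the samples, that library. The arrangements are too few for imidazoles minus triazoles (8 of 10, real 1, highest other 5). Counts of 0 here are from edgeR, with unadjusted counts and DESeq2 counts given with each comparison.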

How the results depend on the processing

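The tests without DMSO replicate 1 for chemicals of plates 2 and 3, for lists and for lowest active doses, the comparison of plates without a DMSO library, those with the library score and those without a lower dose were chosen after seeing the data. Numbers are called probes unless stated, and the cause of a change was not tested, except that fewer libraries or more probes were used where the setting says so. No paired analysis was possible, as replicate numbers pair nothing.

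DESeq2 moved counts by more than 1.5 times to these values: acetochlor 2, alachlor 188, ametryn 123, bensulide 7, bisphenol A 18, carbaryl 11, cyclanilide 1, cyproconazole 553, cyprodinil 16, DEHP 15, dichlobenil 15, dithiopyr 1114, fludioxonil 8, flusilazole 39, imazalil 578, oxadiazon 60, PFOA 298, PFOS 7, S-Bioallethrin 191, simazine 159, tetraconazole 29, triadimefon 61, triflumizole 58, triticonazole 164, chloroacetamides 29, perfluorinated acids 136, triazines 353, PFOA minus PFOS 341, ametryn minus simazine 7, imidazoles minus triazoles 14, 17beta-estradiol 2, dexamethasone 11, GW4046 31, oltipraz 42, pregnenolone-16alpha-carbonitrile 47, sulforaphane 850 and WY14643 36. Without a plate term they were ametryn 26, bensulide 2, carbaryl 2, cyproconazole 416, dichlobenil 5, dithiopyr 204, fludioxonil 9, imazalil 301, oxadiazon 8, PFOA 508, S-Bioallethrin 182, triadimefon 31, triflumizole 20, triticonazole 1.9e+02, chloroacetamides 1, perfluorinated acids 188, imidazoles minus triazoles 3, 17beta-estradiol 1, dexamethasone 4, GW4046 7, oltipraz 7, pregnenolone-16alpha-carbonitrile 7 and WY14643 30. With a dose score by rank they were alachlor 1, bensulide 0, cyproconazole 2, dithiopyr 82, flusilazole 2, hexaconazole 1, imazalil 0, PFOA 43, simazine 3, tetraconazole 4, triflumizole 3, chloroacetamides 157, perfluorinated acids 17, triazines 546 and imidazoles minus triazoles 0. Without the highest doses they were ametryn 0, bensulide 0, bisphenol A 625, carbaryl 0, cyproconazole 10, cyprodinil 0, dithiopyr 8, fludioxonil 0, flusilazole 2, hexaconazole 0, imazalil 0, PFOA 24, S-Bioallethrin 17, tetraconazole 2, triflumizole 0, triticonazole 0, azoles 142, perfluorinated acids 6, triazines 0, PFOA minus PFOS 58 and imidazoles minus triazoles 0. With no filter they were dithiopyr 171, imazalil 28, PFOA minus PFOS 66, imidazoles minus triazoles 0, dexamethasone 3 and oltipraz 4, and with DESeq2's size factors triticonazole 0, perfluorinated acids 52 and dexamethasone 2.

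With the library score as a covariate they were alachlor 1, ametryn 26, bensulide 0, cyproconazole 312, cyprodinil 8, dichlobenil 1, dithiopyr 206, fludioxonil 0, flusilazole 12, imazalil 4, isoxaflutole 1, oxadiazon 9, PFOS 1, S-Bioallethrin 111, simazine 1, tetraconazole 11, triadimefon 27, triflumizole 30, triticonazole 10, perfluorinated acids 89, triazines 359, PFOA minus PFOS 301 and imidazoles minus triazoles 16. With the score and without DMSO replicate 1 they were acetochlor 40, alachlor 13, ametryn 1042, bensulide 62, carbaryl 196, cyclanilide 5, cyproconazole 1786, cyprodinil 73, DEHP 405, dichlobenil 155, dithiopyr 1968, etoxazole 4, fludioxonil 23, flusilazole 256, hexaconazole 159, imazalil 708, isoxaflutole 3, oxadiazon 867, PFOA 1091, PFOS 89, S-Bioallethrin 1212, simazine 603, tetraconazole 265, triadimefon 395, triclosan 1, triflumizole 479, triticonazole 1359, chloroacetamides 40, perfluorinated acids 459, triazines 1236, PFOA minus PFOS 1380, ametryn minus simazine 201, imidazoles minus triazoles 223 and lists of classes 32. With an estimated correlation the called lists were lists of trends 49, lists of classes 3 and lists of differences 6.

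Leaving out 1 DMSO library, 1 dose of a trend below the highest or, for the azoles and chloroacetamides alone, 1 class member at a time (the highest dose is given above) gave these lowest and highest counts for trends: acetochlor 0 to 0, alachlor 0 to 1, ametryn 1 to 85, bensulide 0 to 8, bisphenol A 0 to 0, carbaryl 0 to 9, cyclanilide 0 to 1, cyproconazole 63 to 989, cyprodinil 3 to 21, DEHP 0 to 19, dichlobenil 0 to 23, dimethenamid 0 to 0, dithiopyr 156 to 1435, etoxazole 0 to 0, fludioxonil 0 to 8, flusilazole 2 to 65, hexaconazole 1 to 10, imazalil 0 to 1166, isoxaflutole 0 to 1, oxadiazon 0 to 147, PFOA 34 to 414, PFOS 0 to 12, S-Bioallethrin 9 to 324, simazine 0 to 27, tetraconazole 7 to 51, triadimefon 7 to 106, triclosan 0 to 0, triflumizole 3 to 56 and triticonazole 0 to 352. For classes they were azoles 1165 to 2891, chloroacetamides 0 to 10, perfluorinated acids 22 to 166 and triazines 34 to 310, no member being left out of the perfluorinated acids or the triazines, and for differences acetochlor minus alachlor 0 to 0, PFOA minus PFOS 102 to 445, ametryn minus simazine 0 to 1 and imidazoles minus triazoles 1 to 39. For reference chemicals they were 17beta-estradiol 0 to 1, dexamethasone 0 to 14, GW4046 0 to 105, oltipraz 0 to 144, pregnenolone-16alpha-carbonitrile 0 to 166, sulforaphane 719 to 3147, TCPOBOP 0 to 2, testosterone 0 to 0 and WY14643 3 to 59, and for plates 0 to 0. Where such a range is not 0 to 0, its highest count came without DMSO replicate 1. Called lists without that library were 179 for trends, 29 for classes and 19 for differences, and lowest active doses were 3 to 3.

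Falls of the azoles reversed without DMSO replicate 1, to 0.075 for Pfdn1, 0.78 for Ccng1, 0.0184 for Cox20, 0.11 for Pfn1, 0.67 for Timm9, 0.40 for Ugt1a1. With the score also in the model they went to 0.53 for Ccng1, 0.0331 for Cox20, 0.20 for Pfn1, 0.57 for Timm9, 0.35 for Ugt1a1. Over all settings that leave out 1 DMSO library or 1 azole the ranges were -5.16 to 0.075 for Pfdn1, -5.15 to 0.78 for Ccng1, -3.49 to 0.0184 for Cox20, -3.39 to 0.11 for Pfn1, -3.11 to 0.67 for Timm9, -1.63 to 0.40 for Ugt1a1. Without the highest doses imazalil went to -0.11 for Atf3 and -1.26 for Ddit3, and imidazoles minus triazoles to -0.28 for Srxn1. The alternative without very shallow libraries, set relative to the median DMSO total, was not run, since no dose library is that shallow, and the library score was not run for single references. Sulforaphane's library held 582071 counts.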

Other observations

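The test without DMSO replicate 1 was chosen after seeing the data for chemicals of plates 2 and 3, and so were the genes in this part.

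With dithiopyr, Cyp4a1 and Ehhadh were higher at middle doses than at the highest dose. Cyp4a1 was at 250 CPM at 3.7 µM, 222 at 11.1 µM and 48.2 at 33.3 µM, against 41.5 ± 6.94 in DMSO (SD, n = 9). Ehhadh was at 36.3, 41.9 and 1.9 at these doses. The trend test assumes a steady course over doses, and this shape was not tested for these genes or for the other genes induced through PPARα.

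Several probes were called with many chemicals once DMSO replicate 1 was left out. Gsta2 was higher with 14 chemicals in place of 1 and Ugt2b1 with 13 in place of 7. Acly was lower with 12 in place of 2, Tkfc with 10 in place of 1, and Rem1 with 10 in place of 4. The trends share their DMSO libraries, so these counts are not independent.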
